A study of Shewanella loihica PV-4 with 6 samples.

How the data were processed

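Total RNA of Shewanella loihica PV-4 wild type and hemH1 deletion cells was hybridised to arrays, 3 per strain. Per the labels, RNA was labelled with Cy5 and genomic DNA with Cy3 by random priming. The deposited files hold 1 intensity per spot and no second channel, so the deposited values were used as RNA intensity without a ratio to DNA. The deposited intensity of a gene is the arithmetic mean of its spots, and no spot lies below 50. A signal-to-noise score per spot is also deposited by the authors, and how noise was taken is not given in the sources used here. Scanner, background treatment and normalization are not given in the sources used here either, and the array medians differ, so no scaling between arrays had been applied that equalises them. In the authors' value table of the series, 0 cells differed from the mean spot intensity by more than 1e-09, so its scale is linear and not centred and its column medians are those of the arrays. One comparison was made, with the deletion strain set against the wild type.

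Each array held 34590 spots for 3849 genes, 3835 genes with 9 spots, 11 with 6 and 3 with 3. Between 0.393% and 2.49% of the spots of an array stood at the floor of 50. The files carry no background column, so no background correction was made, and no saturation mark, so bright spots were kept as they are. Spot intensities were taken to log2 and quantile scaled between arrays, and the spots of a gene were averaged on the log2 scale. Because the strains' arrays differ in brightness, quantile scaling assumes that the distribution of RNA levels is the same in both strains, and a shift of all genes in one direction would be removed. Strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all 3849 genes and a threshold of 0.05. Genes named by identical products are told apart by the identifiers of the files, and no genome or locus tags were used here, so no coordinates are given. Neighbouring genes are those with consecutive identifiers.

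A gene was called not above background in a strain when none of its spots reached a signal-to-noise ratio of 2 on any of the 3 arrays, a rule set after seeing the data. This held for 23 genes in the wild type only, 65 in the deletion strain only and 17 in both. For such a gene a fold is a lower bound. By a wider rule, chosen later, under 0.5 of the spots reached that ratio on each of the 3 arrays, which held for 95 genes in the wild type only, 390 in the deletion strain only and 243 in both. The bound sets the mean of the bright strain against the mean of, per array, the higher of the gene's own value and the lowest value among genes with a mean signal-to-noise ratio of at least 2.

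The 20 gene lists were fixed before the data were examined and were matched through the product names of the files. The list with 1 gene was not tested (minimum 3). Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 19 lists, and again with an estimated correlation and with fry. Products that a pattern caught by accident stayed in the main result, and the lists were also run without them. Named genes were fixed by rule before the data were examined. They are both ferrochelatases, the 10 largest rises and falls among called genes whose strains do not overlap, leaving out hemH1, up to 3 called members of each list by size of change, and every called member of the haem biosynthesis and sigma factor lists. The rule left out both ferrochelatases from the largest changes, since the files do not say which is hemH1.

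The fit was tested on simulated arrays made from the wild type spot means, the residual spread of each gene and its spot noise, over 3849 genes. With 50 genes changed at each of 4 sizes, 64.0% of those raised by 1 log2 unit, 60.0% of those lowered by 1, 94.0% of those raised by 2 and 90.0% of those lowered by 2 were recovered, and 3.14% of calls were false. The noise of the simulation and the recovery it had to reach were revised after first runs had recovered fewer genes than required, so these shares describe the test and meet no level set beforehand. With no gene changed and the deletion arrays dimmer by 1 log2 unit, 0 genes were called. With changes of the real size and share, assigned to genes at random, 11.4% of calls were false or in the wrong direction with quantile scaling, 1.34% with median centring, 12.4% with cyclic loess and 35.3% without scaling. The simulated brightness difference was a single factor per array, which median centring removes exactly. Quantile scaling stayed the main setting because it had been fixed before the data were examined. A simulated list of 20 genes raised by 1 was called, and 0 of 19 unmoved lists were. In that simulation the deviations of genes were drawn independently and no gene outside the raised list was changed. The absence of false list calls therefore does not extend to lists with correlated members, such as ribosomal proteins (estimated correlation 0.42), or to a broad change.

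Alternatives were median centring, cyclic loess, leaving out the dimmest 0.25 of genes by mean, the median of a gene's spots, an intensity trend with robust estimation, a replicate block, the authors' value table and leaving out each array in turn. No scaling between arrays, a filter on the signal-to-noise ratio, the wider rule for background, lists without accidental members, 2 lists with members missed through their spelling, 1 ferrochelatase without 2 stray spots, and 10 further gene groups were chosen after seeing the data. The labels name the replicates as biological.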

Results

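Gene expression was measured in Shewanella loihica PV-4, a marine bacterium that respires metals, in a wild type strain and in a strain lacking hemH1, one of its genes for ferrochelatase. Ferrochelatase inserts iron into protoporphyrin IX, the last step of haem synthesis. Per the labels, the deletion strain accumulated protoporphyrin IX and the wild type did not, and cells of both were collected in late logarithmic phase from rich medium. Each strain was represented by 3 biological replicates, with 1 array each. Each array read 3849 genes, 3835 of them through 9 spots. The wild type arrays were brighter: their median gene intensity was 4056, 3665 and 4258, against 2243, 1732 and 1864 on the deletion arrays. The share of genes with a mean signal-to-noise ratio of at least 2 was 89.0% to 92.6% on the wild type arrays and 78.0% to 85.2% on the deletion arrays. The number of arrays, 3 per strain, limits the precision of every value.

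The comparison asked how transcription differed between the 2 strains. In the deletion strain, 2 receptors for siderophores had the largest rises and the iron transporter FeoB was 51.3-fold higher, while the iron uptake and storage genes as a list went both ways, with 15 higher and 14 lower. Genes for the flagellar basal body, the nickel-iron hydrogenase and a decaheme cytochrome c stood among the largest falls. Most of the genes that make haem precursors were lower, by up to 14.3-fold. Ribosomal protein genes were lower in 51 of 57 cases, with a median log2 change of -1.71.

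The files name 2 genes as ferrochelatase and do not say which of them is hemH1, so both were followed. Ferrochelatase 127513157, whose identifier lies next to that of adenylate kinase, had a mean spot intensity of 4828, 3861 and 4011 on the wild type arrays and 1073, 559 and 1221 on the deletion arrays. After scaling it was 2.56-fold lower in the deletion strain (log2 change -1.36, SE 0.27, limma adjusted p = 0.00157), and its log2 change was -2.39 without scaling between arrays. It was not at background there: 6, 4 and 8 of its 9 spots had a signal-to-noise ratio of at least 2. Ferrochelatase 127512073 had intensities of 1009, 834 and 1115 in the wild type and 726, 3082 and 615 in the deletion strain. It was not at background there either, with 6 of its 9 spots at that ratio on each deletion array. Its log2 change was 0.60 (SE 0.26, adjusted p = 0.0567), which did not pass the threshold. The value of 3082 rested on 2 bright spots, and without the same 2 spots on every array the log2 change was 0.17 (SE 0.23, adjusted p = 0.517, a setting chosen after seeing the data). It did pass with median centring (0.86, adjusted p = 0.0160), with the median of its spots (0.72, adjusted p = 0.00599) and without deletion replicate 1 (0.79, adjusted p = 0.0340), while it was 1.21 with the authors' value table (adjusted p = 0.126) and -0.27 without scaling (adjusted p = 0.374). Where the probes lie in either gene is not given in the sources used here, so neither value checks the deletion.

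**Figure D1:**
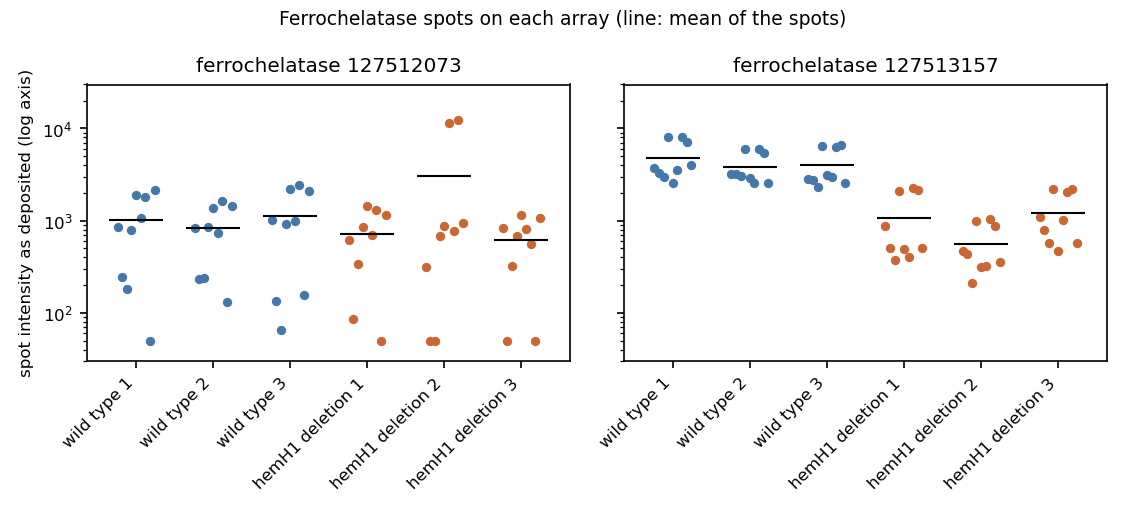
Intensity of each spot of the 2 ferrochelatase genes on the 6 arrays, as deposited and before scaling, on a log axis, with wild type in blue, deletion strain in orange and the mean of the spots as a line. The mean of ferrochelatase 127513157 was lower on each deletion array (at most 1221) than on each wild type array (at least 3861), and the mean of 3082 for ferrochelatase 127512073 on deletion replicate 2 is carried by 2 spots.

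Of the 3849 genes, 2831 differed between the strains at an adjusted p under 0.05, 1478 higher and 1353 lower in the deletion strain. Of these, 1928 differed at least 2-fold and 127 at least 16-fold. The arrays of the strains did not overlap for 2957 genes (76.8%), where chance gives 10%. The largest rises were in 2 TonB-dependent siderophore receptors, outer membrane proteins that take up iron bound to siderophores. Receptor 127514025 stood at a log2 intensity of 7.33 ± 0.04 (SD, n = 3) in the wild type and 15.22 ± 0.70 (SD, n = 3) in the deletion strain, a 237-fold difference. Receptor 127514766 was 183-fold higher. A putative lipoprotein (127511610) was not above background in the wild type and was at least 116-fold higher in the deletion strain. The extracellular solute-binding proteins 127511795 and 127514094, parts of transport systems, were 129-fold and 121-fold higher. A PepSY-associated membrane helix protein (127512113) was 93.0-fold, a BFD/(2Fe-2S)-binding protein (127511486) 92.9-fold and malate synthase 127513487, an enzyme of the glyoxylate shunt, 90.7-fold higher. The other 2 of the 10 largest rises were hypothetical proteins, at 117-fold and 84.1-fold. The adjusted p of these 10 genes was at most 2.13e-06, and the SE of their log2 changes ran from 0.15 to 0.50.

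The largest fall was in the b-type cytochrome subunit of a nickel-iron hydrogenase (127512691). It was not above background in the deletion strain and was at least 119.5-fold lower there. The flagellar rod proteins FlgB and FlgC were 99.6-fold and 69.8-fold lower, and the rod modification protein next to them (127512278) 64.6-fold. Decaheme cytochrome c 127511851 was 67.1-fold lower. Enoyl-CoA hydratase/isomerase 127512600, of a family that acts in fatty and branched-chain acid degradation, was 65.7-fold lower. Enoyl-CoA hydratase/isomerase 127513500 was not above background in the deletion strain and was at least 65.2-fold lower. A molybdopterin oxidoreductase (127510998) was 64.7-fold lower, and 2 hypothetical proteins were 76.7-fold and 67.4-fold lower. The adjusted p of these 10 genes was at most 9.14e-08, and the SE of their log2 changes ran from 0.15 to 0.24. By a wider rule for background, under 0.5 of a gene's spots at a signal-to-noise ratio of 2 on each array of a strain, the folds of 15 of these 20 genes were lower bounds. The bound was below the fold given above for 4 of them: at least 231-fold for receptor 127514025, 70.2-fold for hypothetical protein 127511609 (84.1-fold), 72.1-fold for FlgB and 73.8-fold for hypothetical protein 127510997 (76.7-fold). The folds of 10 other named genes were lower bounds by that rule, equal to the folds given here. Of 83 named genes, 13 had spots above 0.9 of the highest spot of their array, 7 of them among these 20, with 8 of 27 spots of 127511795 in the deletion strain. A limit at the upper end of the scale is not excluded for the folds and order of these 13. Both checks were chosen after seeing the data. The median log2 change of all genes was 0.09 with quantile scaling, 0.28 with median centring and -0.84 with no scaling between arrays, a setting chosen after seeing the data. Without scaling 552 genes were called higher and 2170 lower, so 20.3% of calls were higher, against 52.2% with quantile scaling. Among the 3484 genes past the signal-to-noise filter, also chosen after seeing the data, 1291 were called higher and 1335 lower (49.2% higher). On simulated arrays with changes of the same size and share, 11.4% of calls with quantile scaling were false or in the wrong direction, above the nominal 0.05. With median centring the share was 1.34%. The simulated changes were assigned to genes at random, and the simulated brightness difference was one that median centring removes exactly. These shares are therefore not error rates of the real arrays.

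**Figure D2:**
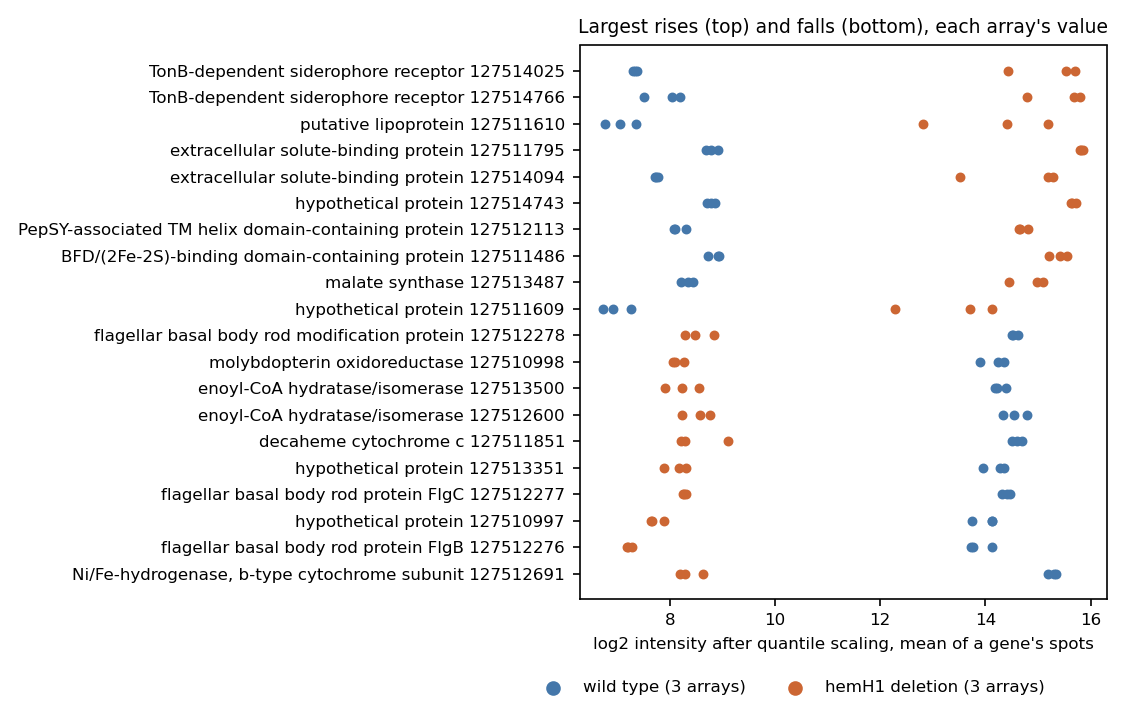
Log2 intensity after quantile scaling, averaged over a gene's spots, of the 10 largest rises and 10 largest falls, with each point 1 array, wild type in blue and deletion strain in orange. The 3 values of each strain do not overlap for any of the 20 genes shown, and siderophore receptor 127514025 moved from a mean of 7.33 to 15.22.

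Among 17 haem biosynthesis genes, 10 were lower, 2 were higher and 5 did not pass the test. The list held both ferrochelatases, 127513157 among the lower genes and 127512073 among those that did not pass. One of them is the deleted gene, so the counts and the list test are not free of the deletion itself. The median log2 change of the list was -1.19 (camera adjusted p = 0.0256, or adjusted p = 0.41 with an estimated correlation). The 3 enzymes that make aminolevulinic acid and porphobilinogen were all lower: glutamyl-tRNA reductase 5.49-fold, glutamate-1-semialdehyde aminotransferase 3.55-fold and delta-aminolevulinic acid dehydratase 6.31-fold. Coproporphyrinogen III oxidase was 11.6-fold lower for gene 127511008 and 2.28-fold for gene 127514648. The 3 genes named protoporphyrinogen oxidase, whose product is protoporphyrin IX, were 14.3-fold (127511612), 5.59-fold (127510960) and 4.68-fold (127510958) lower. Uroporphyrinogen decarboxylase was 1.51-fold lower (adjusted p = 0.0415). That call was lost with median centring (adjusted p = 0.158), without wild type replicate 1 (adjusted p = 0.123) or 2 (0.115), and without deletion replicate 1 (0.0754) or 2 (0.133). Both genes that rose, at 6.52-fold (127511051) and 1.64-fold (127511304), are protoheme IX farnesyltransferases, which convert haem into haem o and do not make it. By the wider rule for background 127511304 was above it in neither strain, and its call was lost with the median of a gene's spots (adjusted p = 0.106) and without scaling (0.97).

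Of 10 cytochrome c maturation genes, which deliver and attach haem to cytochromes, 6 were higher, 2 were lower and 2 did not pass (camera adjusted p = 0.454). Haem exporter CcmB was 3.95-fold higher, while CcmF was 2.78-fold and a cytochrome c biogenesis protein (127511129) 2.10-fold lower. Of 39 genes matched as c-type cytochromes, 17 were lower, 10 were higher and 12 did not pass (adjusted p = 0.454, or adjusted p = 0.56 with an estimated correlation). At the preset correlation the list passed without the dimmest genes (median log2 change -1.35, adjusted p = 0.0218). The largest changes among these 39 after that of decaheme cytochrome c 127511851 were rises in subunits II and III of a cytochrome c oxidase. These subunits were matched through the name of the oxidase, which acts on cytochrome c, and are not named as c-type cytochromes. The same holds for 2 cytochrome-c oxidase genes that the list missed through their spelling, with which 12 of 41 were higher (adjusted p = 0.538). The list was not run without the oxidase subunits, so its counts are not of c-type cytochromes alone.

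Of 37 genes for aerobic respiratory oxidases and ATP synthase, 29 were lower, 6 were higher and 2 did not pass, with a median log2 change of -1.56 (camera adjusted p = 5.17e-04, or adjusted p = 0.357 with an estimated correlation). One member, a flagellum-specific ATP synthase, was matched by accident, and without it the adjusted p was 8.57e-04. The 3 largest changes among these 37 ran against the list: cytochrome c oxidase subunit II (127511059), its assembly protein (127511057) and subunit III (127511056), with nearby identifiers, were 17.6-fold, 12.8-fold and 11.1-fold higher. The list missed 3 oxidase genes through their spelling, named after their values were seen: cytochrome-c oxidase 127511058, between those genes, was 22.4-fold higher, cytochrome-c oxidase 127511301, not above background in the wild type, was at least 1.76-fold higher and a cytochrome oxidase assembly protein was 4.67-fold higher. By the wider rule for background 127511301 was above it in neither strain, so by that rule no bound holds for it. With these 3 missed genes 29 of 40 were lower and 9 higher (adjusted p = 0.00871, or adjusted p = 0.425 with an estimated correlation). Of 27 genes matched as anaerobic terminal reductases, 13 were lower, 7 were higher and 7 did not pass (adjusted p = 0.0638). The largest changes were in hydrogenase genes, the b-type cytochrome subunit named above, small subunit HydA at 61.1-fold and the large subunit at 60.4-fold lower, with 4 and 8 of their 27 wild type spots above 0.9 of the highest spot. The pattern of the list takes in hydrogenases, so all 10 genes of the hydrogenase group described below, accessory genes included, are among its 13 lower members. The list was not run without them, so its calls do not speak for terminal reductases apart from hydrogenase. Without 2 subunits of NAD(P) transhydrogenase that were matched by accident, the list passed (adjusted p = 0.0187, or adjusted p = 0.418 with an estimated correlation). It also passed with cyclic loess (adjusted p = 0.0433), without the dimmest genes (0.00477), among genes past the signal-to-noise filter (0.0178) and without deletion replicate 1 (0.0340). Of 23 genes matched to the tricarboxylic acid cycle, 12 were lower, 8 were higher and 3 did not pass (adjusted p = 0.533). Their median log2 change was -0.77 and their mean 0.02. After malate synthase 127513487, the largest changes were in 2-isopropylmalate synthase (19.6-fold higher) and 3-isopropylmalate dehydrogenase (12.9-fold higher), which make leucine and were matched by accident.

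Iron uptake and storage genes went both ways: of 35, 15 were higher, 14 were lower and 6 did not pass (camera adjusted p = 0.496). FeoB, which carries ferrous iron across the inner membrane, was 51.3-fold higher (SE of the log2 change 0.20, adjusted p = 5.63e-08), the largest change after those of the 2 siderophore receptors. Of 8 iron-sulphur cluster assembly genes, 6 were higher, none was lower and 2 did not pass, with a median log2 change of 1.54 (adjusted p = 0.0306, or adjusted p = 0.328 with an estimated correlation). Cysteine desulfurase, which supplies the sulphur, was 4.11-fold higher, and the chaperones HscB and HscA were 3.37-fold and 3.23-fold higher. Of 12 sulphur and cysteine assimilation genes, 5 were higher, 1 was lower and 6 did not pass (adjusted p = 0.454). The regulator CysB was 3.21-fold and the putative sulfate transport protein CysZ 2.90-fold higher, and sulfate transporter YchM was 4.33-fold lower. The call of CysZ was lost without scaling (adjusted p = 0.0696).

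Of 36 genes matched to oxidative stress defence, 18 were higher, 6 were lower and 12 did not pass. The median log2 change was 0.52 (camera adjusted p = 0.0418, or adjusted p = 0.34 with an estimated correlation), and it was -0.17 without scaling. The list held 11 genes matched by accident through letters within words such as deoxyribonuclease, and without them 16 of 25 were higher and 4 lower (adjusted p = 0.0187, or adjusted p = 0.246 with an estimated correlation). A bifunctional methionine sulfoxide reductase, which repairs oxidised methionine, was 26.6-fold higher and a glutathione S-transferase (127514139) 14.4-fold higher, while glutaredoxin 2 was 9.22-fold lower. The call of the list was lost without deletion replicate 2 (adjusted p = 0.0524) or 3 (0.0739), with the median of a gene's spots (0.0622) and without the dimmest genes (0.0744). Of 21 heat shock proteins and proteases, 15 were higher, 3 were lower and 3 did not pass, with a median log2 change of 1.11 (adjusted p = 0.0334, or adjusted p = 0.328 with an estimated correlation), and the call was lost without deletion replicate 3 (adjusted p = 0.0739). The proteases La (127514277), HslU and ClpA were 5.06-fold, 4.86-fold and 4.34-fold higher, with 6 of 27 spots of ClpA above 0.9 of the highest spot in the deletion strain.

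Of 17 envelope stress and outer membrane assembly genes, 8 were higher, 6 were lower and 3 did not pass (camera adjusted p = 0.647). Phage shock proteins PspC (127511472) and PspA (127513424), which respond to damage of the inner membrane, were 28.5-fold and 14.2-fold higher, and the lipoprotein carrier LolA (127514447) was 8.55-fold lower. Of 21 genes of the SOS response and DNA repair, 9 were lower, 8 were higher and 4 did not pass (adjusted p = 0.486). The LexA repressor was 8.67-fold higher (SE of the log2 change 0.49), with deletion arrays spread from a log2 intensity of 13.05 to 15.48. A LexA regulated protein was 17.4-fold lower and RadC (127514409) was 4.43-fold lower. The list for light damage and membrane repair held 1 gene, a cyclopropane-fatty-acyl-phospholipid synthase, with a log2 change of 0.13 (adjusted p = 0.511). A deoxyribodipyrimidine photo-lyase, which repairs DNA in light, had a log2 change of 0.07 (adjusted p = 0.758), and was named after its value was seen. Of 46 genes matched as efflux pumps, 22 were higher, 12 were lower and 12 did not pass (adjusted p = 0.317). Membrane fusion subunits 127512578 and 127514725 of RND transporters were 9.78-fold and 7.27-fold higher, and a potassium efflux protein (127513545) was 7.10-fold higher.

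Of 12 alternative sigma and anti-sigma factors, 6 were higher, 3 were lower and 3 did not pass (camera adjusted p = 0.531). The ECF sigma-24 factor 127513884 was 11.9-fold and the RpoD family sigma factor 127512145 was 5.69-fold higher. An anti-sigma 70 factor was 2.95-fold higher, the anti-ECF sigma factor ChrR 2.71-fold, ECF sigma-24 factor 127512163 2.18-fold and sigma factor 127512405, next to ChrR, 1.78-fold. Without scaling the last 3 of these were not called, and the log2 change of 127512405 was -0.25. An anti-sigma factor antagonist was 2.97-fold lower, sigma factor 127513361 2.65-fold and the flagellar sigma factor 2.35-fold. Of 6 stationary phase genes, 2 were higher, 2 were lower and 2 did not pass (adjusted p = 0.638), with a median log2 change of -0.45 and a mean of 0.06. The carbon starvation protein CstA was 7.75-fold higher, and SurE and a BolA family protein (127513811) were 2.65-fold and 2.33-fold lower. Of 13 mobile element and phage genes, 3 were higher, 2 were lower and 8 did not pass (adjusted p = 0.755). Phage integrases 127511928 and 127512199 were 4.49-fold and 3.59-fold higher, and the transposase ISPpu15 Orf2 was 4.15-fold lower.

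Of 57 genes matched as ribosomal proteins, 51 were lower, 3 were higher and 3 did not pass. The median log2 change was -1.71 (camera adjusted p = 4.61e-09, or adjusted p = 0.496 with an estimated correlation). The largest falls were in S16 (11.3-fold), L19 (9.41-fold) and L13 (8.80-fold). Among the 54 members left without 3 ribosome-associated proteins of the S30EA type, 50 were lower. Of 74 flagella and chemotaxis genes, 42 were lower, 14 were higher and 18 did not pass. The median log2 change was -0.70 (adjusted p = 4.87e-04, or adjusted p = 0.328 with an estimated correlation), and FlgB, FlgC and the rod modification protein fell most. Adjusted over the list alone, the counts equalled those over all genes except in 2 lists: 17 iron uptake and storage genes were then higher and 10 genes of the SOS response and DNA repair lower. With an estimated correlation 0 of the 19 lists passed with camera (lowest adjusted p = 0.328), 2 had an unadjusted p under 0.05, and 15 passed with fry, which does not compare a list with other genes. The lists for cytochrome c maturation, sigma factors, iron uptake, envelope stress, efflux and sulphur had medians above 0 with quantile scaling and below 0 without scaling. For c-type cytochromes the median was -0.09 with quantile scaling, 0.14 with median centring and -1.35 without the dimmest genes.

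**Figure D3:**
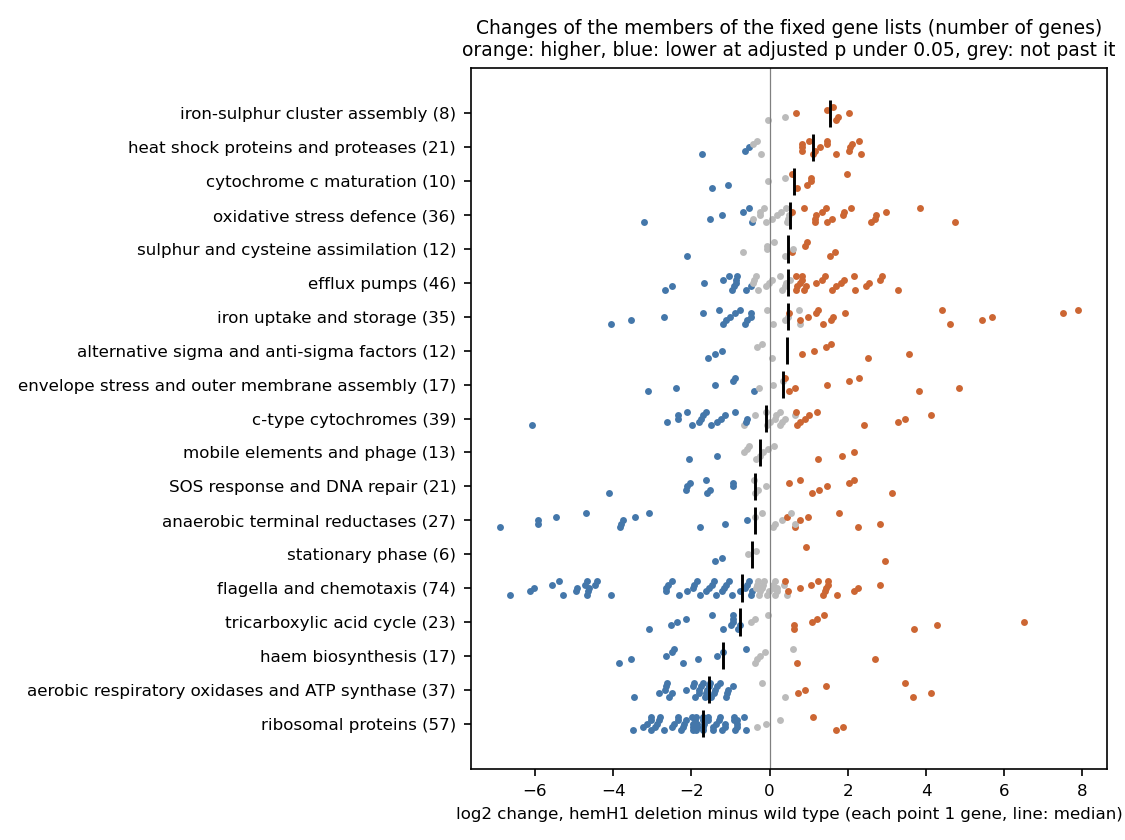
Log2 change (deletion strain minus wild type, quantile scaling) of each member of the 19 gene lists fixed before the data were examined, with orange points higher and blue points lower at an adjusted p under 0.05, grey points not past it, and a black line at the list's median. The medians of ribosomal proteins (-1.71) and of aerobic respiratory oxidases and ATP synthase (-1.56) are the lowest, and that of iron-sulphur cluster assembly (1.54) is the highest.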

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

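No scaling, the signal-to-noise filter, the wider rule for background, lists without accidental members or with missed ones and the ferrochelatase without stray spots were settings chosen after the results were seen. The count of 2831 changed genes ran from 2192 (without the dimmest 0.25 of genes, 2887 genes tested) to 2868 over the other settings, and from 2618 to 2857 when 1 array was left out, with 1360 to 1488 higher and 1249 to 1369 lower. Without scaling 552 were higher and 2170 lower, and of the 2722 calls 1934 were also calls of the main setting, 1905 of them in the same direction; the all-gene median of -0.84 there moves with the lower brightness of the deletion arrays. Of 1208 values of the other named genes under the settings, 1196 kept direction and call, 11 lost the call and 1 turned: sigma factor 127512405 at -0.25 without scaling. Ferrochelatase 127512073 passed the threshold at 0.86 with median centring, 0.72 with the median of spots and 0.60 with the replicate block, stood at 1.21 with the authors' value table (adjusted p = 0.126) and at 0.33 to 0.79 with 1 array left out, and turned to -0.27 without scaling, below 0 as were most genes there. Ferrochelatase 127513157 ran from -1.66 to -1.11 with 1 array left out and was -2.39 without scaling. The number of lists called, 7, was 0 with an estimated correlation and 15 with fry, and 5 to 8 with 1 array left out. Fry does not compare a list with other genes, whereas camera with an estimated correlation still does. Correlation among members did not account for every lost call. The estimate lay below the preset 0.01 for iron-sulphur cluster assembly (-0.083), heat shock (-0.018) and oxidative stress defence (0.0096). It lay above 0.01 for the other called lists. The unadjusted camera p still rose for iron-sulphur cluster assembly, from 0.00806 to 0.0518. For mobile elements and phage the median turned only with median centring (0.029, from -0.24). The direction given by the test turned there and also, with the median still below 0, without the dimmest genes (-0.041) and with fry (-0.24). Likewise only the test's direction turned for the tricarboxylic acid cycle with fry (-0.77) and without scaling (-1.48) and for stationary phase without scaling (-1.16). None of these passed the threshold, and the cause was not tested. Of 361 list values 329 were the same, 12 lost and 14 gained the call and 6 turned, and of 170 values of the 10 added groups 149 were the same, 10 lost and 11 gained it, 7 of the losses with an estimated correlation. By the wider rule for background the fold of FlgB was at least 72.1, from 99.6.

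The replicate block gave 2804 changed genes. With it uroporphyrinogen decarboxylase no longer passed (-0.59, adjusted p = 0.0543) and the added purine and pyrimidine group passed (-1.07, adjusted p = 0.0336). Same-numbered arrays had correlations of their deviations of 0.08, -0.03 and -0.01, and not every array went best with its own number, so the numbers are not taken to pair the cultures. A ratio to genomic DNA, its loess and normexp were not run, because the files hold 1 channel and no background column. Signal over background limits genes that were dim in the deletion strain, where 20.6% to 27.9% of spots lay under a signal-to-noise ratio of 2, against at most 16.7% in the wild type.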

Other observations

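The groups in this part were put together after the largest changes had been seen, and those for arginine, branched-chain amino acids, acyl-CoA degradation and hydrogenase contain genes whose values prompted them, so their direction is no independent evidence. Among amino acid synthesis genes, most of those for arginine, branched-chain amino acids and threonine, histidine and aromatic amino acids were higher in the deletion strain, and those for lysine went both ways. Of 8 arginine synthesis genes 7 were higher, with ornithine carbamoyltransferase at 68.0-fold (a lower bound by the wider rule for background) and acetylglutamate kinase at 65.4-fold. A bifunctional aminotransferase of the same list (127511512) was 4.18-fold lower. The genes with the next identifiers, arginine N-succinyltransferase (5.88-fold lower) and succinylglutamic semialdehyde dehydrogenase (11.6-fold lower), are in the amino acid degradation group below. Of 17 genes for branched-chain amino acids and threonine 15 were higher, such as the acetolactate synthase 2 regulatory subunit at 72.2-fold and homoserine kinase at 42.6-fold. All 8 histidine synthesis genes were higher, between 2.72-fold and 10.1-fold, as were 12 of 15 for tryptophan and the aromatic pathway, with 3 lower. Of 8 lysine and diaminopimelate genes 4 were higher and 2 lower. Camera gave adjusted p = 6.34e-04 for arginine, 3.73e-06 for branched-chain amino acids and threonine, 6.28e-04 for histidine, 0.0366 for aromatic and 0.374 for lysine synthesis over these 10 groups. With an estimated correlation the adjusted p was 0.258, 0.208, 0.252, 0.212 and 0.528. The aromatic call was lost with median centring (adjusted p = 0.0502), without deletion replicate 2 (0.0535) and without scaling (0.0705), and the lysine median of 0.59 was -0.35 without scaling.

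Of 22 amino acid degradation genes 13 were lower and 2 higher (adjusted p = 0.00274, or adjusted p = 0.129 with an estimated correlation), among them glycine dehydrogenase at 10.7-fold and L-threonine 3-dehydrogenase at 11.1-fold. Of 31 acyl-CoA and branched-chain acid degradation genes 15 were lower and 11 higher (adjusted p = 0.0871, or adjusted p = 0.264 with an estimated correlation). At the preset correlation that group passed without the dimmest genes (adjusted p = 0.00354) and with the signal-to-noise filter (0.0230). The lower ones included 6 with neighbouring identifiers, from acetyl-CoA acetyltransferase 127512596 (24.5-fold) to 3-hydroxyisobutyrate dehydrogenase 127512601 (25.7-fold). All 10 hydrogenase genes were lower, between 8.42-fold and at least 119.5-fold (adjusted p = 1.45e-06, or adjusted p = 0.0533 with an estimated correlation). Of 35 translation factors and aminoacyl-tRNA synthetases 28 were lower and 2 higher (adjusted p = 3.73e-06, or adjusted p = 0.208 with an estimated correlation), with elongation factor Ts at 14.8-fold and phenylalanyl-tRNA synthetase subunit beta at 19.7-fold. Of 22 purine and pyrimidine synthesis genes 13 were lower and 3 higher (adjusted p = 0.0502, or adjusted p = 0.528 with an estimated correlation). At the preset correlation the group passed with the median of a gene's spots (0.0409), with the authors' value table (0.0377) and without wild type replicate 1 (0.0369), wild type replicate 2 (0.0466) or deletion replicate 3 (0.0127).

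Of the tests that follow, the comparison of rank correlations and that of arginine, branched-chain, threonine and histidine genes without scaling were chosen after the result was seen. The first pattern was the breadth of change, 2831 of 3849 genes. Array brightness or a monotone scale would keep the order of genes, but the highest Spearman correlation of raw gene intensities between strains was 0.616, against 0.941 to 0.986 within a strain. Independent noise of single genes would leave neighbours unrelated, but the changes of 3834 pairs with consecutive identifiers correlated at 0.526, against -0.05 to 0.05 in 1000 random orders. Chance in the grouping of the arrays stays open: 1 of the 10 splits into 3 and 3, the real one, called as many genes. The highest other split called 0 with limma (at most 19 genes at an unadjusted p under 0.05). Every other split mixes arrays of both strains on each side, which puts the strain difference into the spread. Calling 0 genes was therefore likely in advance, and 10 splits are too few for a share under 0.05. Strain and any difference in growth between the cultures go together in this design. The same holds for any difference in the handling of the wild type and deletion arrays, whose brightness differed.

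The second pattern was that gene lists moved together, with 7 of 19 called. In this case 2 of the 10 splits, the real one included, called as many lists, and the highest other split also called 7. With 10 splits no share under 0.05 can be had, and each other split sets 2 arrays of one strain and 1 of the other against the reverse, so it carries part of the strain difference and is no count without one. The loss of all 7 calls under an estimated correlation (0 lists) leaves open how far the lists differ from other genes. It did not come from correlation among members alone, since the estimate for iron-sulphur cluster assembly (-0.083) lay below the preset 0.01. The added hydrogenase group had an estimate of -0.047, and its unadjusted camera p still rose from 1.45e-07 to 0.00533. The p-values given with an estimated correlation therefore differ from those at the preset one by more than a correction for correlation.

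The third pattern was the higher level of most arginine, branched-chain, threonine, histidine and aromatic synthesis genes, in groups of which none passed with an estimated correlation. Without scaling between arrays the pooled median log2 change of arginine, branched-chain, threonine and histidine genes was 2.64 (95% bootstrap interval 1.44 to 3.74, 33 genes). That pool contains genes whose values prompted it, so it shows only that the pooled rise remained without scaling. Histidine genes were not tested alone. Scaling stays open for the pool of histidine, aromatic and lysine genes (0.49, interval -0.30 to 0.89, 31 genes). The bootstrap intervals here are over genes and may be too narrow, because members of some groups were correlated. The estimated correlation was 0.62 for arginine, 0.21 for branched-chain and threonine and 0.51 for histidine, against 0.02 for aromatic and 0.06 for lysine genes. A shortage of amino acids in the deletion cultures may be a candidate explanation: it predicted a rise in histidine, aromatic and lysine genes, whose values had not been looked at, and their pooled median was 1.24 (interval 0.80 to 1.84), though by group it was 2.31 for histidine, 1.19 for aromatic and 0.59 for lysine genes, the last not called (adjusted p 0.374) and at -0.35 without scaling. Slower growth of the deletion cultures stays open, since the median of translation factors and aminoacyl-tRNA synthetases, -1.83 (interval -2.10 to -0.84), was to be expected from the fall of ribosomal proteins already known and says nothing of the synthesis genes. Neither can be separated here from the deletion itself.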
